A study of Homo sapiens with 9 samples.

How the data were processed

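RNA of MDA-MB-231 cells was measured on 9 Affymetrix whole-transcript arrays, 3 each of control cells, cells given the *Boswellia serrata* extract at 128 µg/ml and cells given 3-O-acetyl-β-boswellic acid at 46 µg/ml, for 6 to 8 h. Groups and replicate numbers came from the labels. The deposited values were taken as log2, with 1 value for each of 53617 probe sets per array. They were made with Affymetrix Expression Console, per the submitters' processing notes, with the version not given in the sources used here. The log base, the summarisation and the normalization between arrays are not stated either, and fold changes hold with the base taken as 2. At most 4.74% of values were identical between any 2 arrays, so no array was a copy of another.

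Probe sets were named through the platform's annotation, which held 25713 of them, 23871 with 1 gene symbol and 1842 with several. The other 27904 were in no row of it and are unnamed here. Symbols were updated through the gene ID against the RefSeq gene table of assembly GRCh38.p14, used only for names, which changed 90 symbols. Probe sets with 1 symbol and at most 1 gene ID, 23862 in all, were used, and for the 630 genes with more than 1 the probe set with the highest mean was kept, leaving 22389 genes. Probe sets with several genes were left out of the gene tests, so HSPA1A, HSPA8 and HSP90B1 are not analysed here. Genes with near-identical copies, such as histones, metallothioneins and ribosomal proteins, may share probes. No detection measure was used here, so whether a dim probe set lies above background is not known. The mean log2 level of 383 olfactory receptor genes, 2.39, was taken as a guide after the values were seen, and where a gene's dimmer group lay at or below it the fold of the measured levels is written as at least that large. Folds of other genes with a level under the array medians of 2.991 to 3.096, such as H2BC18, H2BC11 and MT1F, are also open to understatement.

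No further normalization was applied. A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 comparisons shared 1 estimate of the spread with 6 residual degrees of freedom and a mean of 3.54 prior degrees of freedom. The p-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Values after ± are standard errors of the limma fit unless given as SD, and intervals are 95% intervals of the same fit.

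Gene lists numbered 37 and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists. They covered stress responses, such as the PERK and ATF4 arm of the integrated stress response (ISR), lipid metabolism, cell death, signalling, growth, energy metabolism, the matrix and markers of other cell types, and each is named with its result. No list call was kept when the correlation was estimated for each list, in any comparison.

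The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took the 8 highest and 8 lowest log2 fold changes (6 and 6 for acid against extract) among genes called whose 3 treated arrays all lay beyond the 3 arrays of the other group, passing over unnamed loci, open reading frames, antisense, microRNA and SNORD genes. It added up to 3 members with the largest change of each list called, and, against control, HSPA5, DDIT3, ATF4, ATF3, XBP1, TRIB3, CHAC1, HMOX1, CDKN1A, MYC, ALOX5 and CYP1A1, which are 12 of the 14 genes fixed there, the others being not reported here. Other genes are named where a count was small, and these, called named post hoc, were chosen after their values were seen.

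On simulated data with 50 genes changed at each size among 22389, the procedure recovered 92% of log2 changes of 1 and 14% of 0.5 for the extract, 78% and 8% for the acid and 84% and 12% for the difference. It recovered at least 98% of changes of 2, with 8, 9 and 4 false calls. As both treatments share controls, unchanged groups were simulated 100 times with shared controls and equal spread. Same-numbered arrays of different groups were not treated as pairs.

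Alternatives were quantile normalization, centring each array on its median, trend and robust variance moderation, array weights, leaving out the genes below the median level, testing all probe sets, the mean of a gene's probe sets, the replicate number as a block, only the 6 arrays of the groups compared, leaving out each array in turn, camera with an estimated correlation and limma's fry, a rotation test of whether a list's genes move one way.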

Results

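Gene expression was measured on Affymetrix whole-transcript arrays in MDA-MB-231, an established human breast cancer cell line. Total RNA came from 3 groups with 3 arrays each. The control group received neither test substance. Another group received 128 µg/ml of a *Boswellia serrata* (Indian frankincense) preparation dissolved in ethanol and called the extract. The last received 46 µg/ml of 3-O-acetyl-β-boswellic acid, a pentacyclic triterpene acid of that resin, dissolved in DMSO and called the acid. Exposure lasted 6 to 8 h, and each dose was the LC50 found at 24 h, so the doses differed by mass and the solvents differed too (each below 0.5%). The vehicle of the control cultures is not given in the labels. The study's title names stress of the endoplasmic reticulum (ER), the unfolded protein response and programmed cell death, so the comparisons ask which such genes each substance changed and where the 2 differed. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

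Of the 9 arrays, 8 had mean log2 intensities of 3.806 to 3.859 over all 53617 probe sets. The first acid array stood apart, with a mean of 3.613 and an upper quartile of 4.538 against 4.943 to 5.081 elsewhere. The median SD of a gene was 0.129 in control, 0.12 with the extract and 0.229 with the acid. The shared estimate of the spread therefore tends to understate that of the acid, and p-values of the acid's comparisons may be too small. On the first principal component, which held 48.15% of the variance, the acid arrays lay at 70.73, 34.07 and 7.766, whereas control lay at -25.86 to -21.04 and the extract at -17.49 to -12.2.

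**Figure D1:**
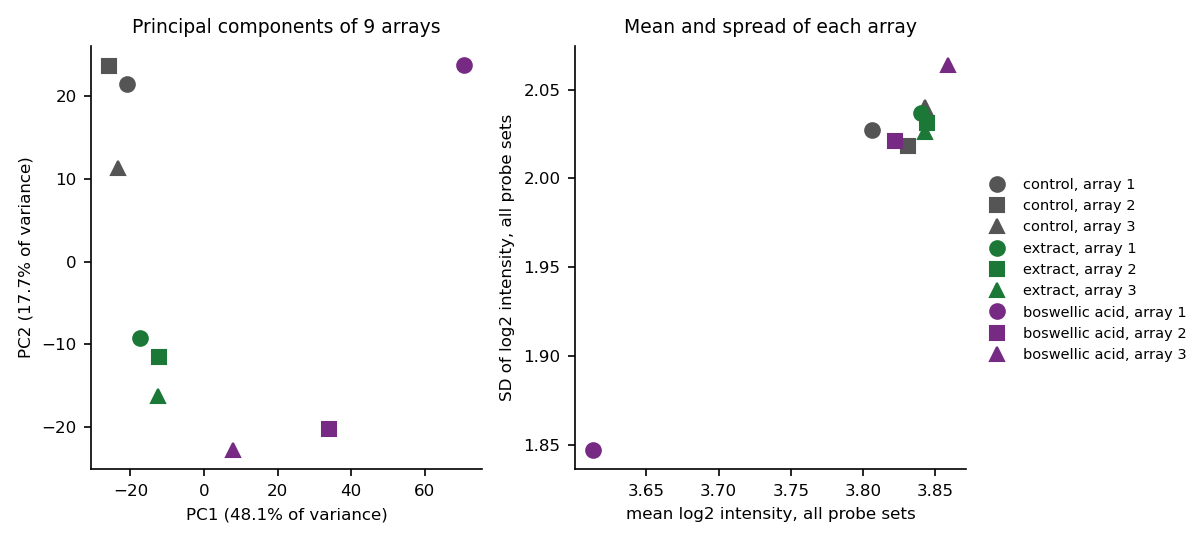
Left, position of the 9 arrays on the first and second principal components, with the share of variance on each axis. Right, mean against SD of the log2 intensity of all probe sets, where the first acid array lies at a mean of 3.613 and all others at 3.806 or above.

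The extract raised genes of ER stress, amino acid stress and oxidative stress. HMOX1, which encodes haem oxygenase 1, rose 23.9-fold, from a log2 level of 5.31 ± 0.056 to 9.89 ± 0.087 (mean ± SD, n = 3 arrays each; log2 fold change 4.58 ± 0.14 SE, adjusted p = 1.1e-06). CHAC1, a glutathione-degrading enzyme gene, rose 17.4-fold (4.12 ± 0.2, adjusted p = 1.4e-05). DDIT3, which encodes the ER stress transcription factor CHOP, rose 14.6-fold (3.87 ± 0.28, adjusted p = 0.00015), from 3.45 ± 0.26 to 7.32 ± 0.29. SESN2, a stress-inducible sestrin gene, rose 14.5-fold (adjusted p = 5.4e-05), the immediate early gene EGR1 12.9-fold (adjusted p = 1.1e-06), and the cysteine synthesis gene CTH 10.6-fold (adjusted p = 1.8e-05). HERPUD1, an ER-associated degradation gene, rose 10.3-fold (adjusted p = 8e-06), and the pseudogene NMRAL2P rose 9.8-fold (adjusted p = 2e-04).

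The transcriptional inhibitor gene ID1 fell to a level 5.89-fold lower than control (log2 fold change -2.56 ± 0.26, adjusted p = 0.0015), and EDN1, which encodes endothelin 1, was 5.26-fold lower (adjusted p = 0.0033). Other falls were VTRNA2-1 (3.64-fold, adjusted p = 0.0049), ADAMTS15 (3.28-fold, adjusted p = 0.0038), SPRY1 and TNS4 (3.16-fold each, adjusted p = 0.00021) and CAVIN2 (3.08-fold, adjusted p = 0.004). SNORA80A was 3.67-fold lower (adjusted p = 0.014), lost without the second or the third control array or the first or the third extract array (adjusted p 0.057 to 0.086).

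Over 22389 genes, limma called 248 with the extract, 202 higher and 46 lower. Of these, 148 rose and 29 fell by at least 1 log2 unit. All 248 had extract values beyond all control values, as did 21.7% of all genes, where chance gives 10%. With quantile normalization 621 were higher and 382 lower, a lower share of 38.1% against 18.5%. Omitting a control array gave 102, 101 and 151 genes, omitting an extract array 118, 97 and 97, and omitting the first acid array, which enters here only through the shared estimate of the spread, 888, all 248 among them.

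In the list of the PERK and ATF4 arm of the stress response (ISR), 17 of 27 genes rose with the extract, and 21 when adjusted over the list alone. The list mean rose by 1.6 log2 units in camera, a competitive gene set test (adjusted p = 1.7e-43; adjusted p = 0.0502 with an estimated correlation). Besides CHAC1, DDIT3 and SESN2, the pseudokinase gene TRIB3 rose 4.67-fold (adjusted p = 0.003). ATF3 rose 2.92-fold (adjusted p = 0.02), lost without any control or extract array (adjusted p 0.067 to 0.12). ATF4 itself had a log2 fold change of 0.599 and did not pass (adjusted p = 0.095). It passed without the first acid array (0.012) and with quantile normalization, median centring, array weights or only the 6 arrays compared (adjusted p 0.0042 to 0.018). Of the 17 calls, 11 also passed without any 1 array, unlike the others (adjusted p 0.051 to 0.19).

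ER chaperones and folding enzymes formed the second group, with 11 of 21 genes higher, 7 of them also without any 1 array, 14 when adjusted over the list alone, and a mean of 1.1 (camera adjusted p = 6.6e-30; adjusted p = 0.0502 with an estimated correlation). HSPA5, the gene of the chief ER chaperone BiP, rose 3.12-fold from 9.79 ± 0.071 to 11.4 ± 0.034 (SD, n = 3 arrays each; adjusted p = 4.7e-05). DNAJB9 rose 7.07-fold (adjusted p = 3.1e-05), the oxidoreductase gene ERO1B 5.85-fold (adjusted p = 1.1e-05) and SDF2L1 5.15-fold (adjusted p = 0.00091). XBP1 rose 2.41-fold (adjusted p = 0.018), lost without any control or extract array (adjusted p 0.07 to 0.11). In the list of ER-associated degradation, 4 of 19 genes rose, 12 when adjusted over the list alone (mean 0.74, camera adjusted p = 3.2e-17; adjusted p = 0.182 with an estimated correlation). HERPUD1 and SEC24D (3.02-fold, adjusted p = 0.00083) passed without any 1 array, whereas the calls of EDEM1 and SEL1L, the latter named post hoc (chosen after its values were seen), were lost without any control or extract array, among others (adjusted p 0.061 to 0.23).

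Of 19 cytosolic aminoacyl-tRNA synthetase genes 5 rose, and adjusted over the list alone 10 rose and 1 fell. The list averaged 0.41 (camera adjusted p = 4.3e-08; adjusted p = 0.504 with an estimated correlation). WARS1 rose 2.84-fold (adjusted p = 0.0051) and GARS1, named post hoc, 1.8-fold (adjusted p = 0.0032). Calls of AARS1, CARS1 and SARS1, the last also named post hoc, were lost without any control or extract array, among others (adjusted p 0.055 to 0.17). Among 15 amino acid transporters 4 rose, 8 when adjusted over the list alone (mean 0.66, camera adjusted p = 1e-10; adjusted p = 0.184 with an estimated correlation). SLC7A11, the cystine transporter gene, rose 8.74-fold (adjusted p = 1.1e-05) and SLC38A2 2-fold (adjusted p = 0.0016). SLC3A2 and SLC38A1 lost their calls without any control or extract array, among others (adjusted p 0.056 to 0.16), and SLC38A1 and SLC38A2 were named post hoc.

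Oxidative, heat and metal stress genes rose as well. Of 25 NRF2 targets 6 rose, each also without any 1 array, with 12 higher when adjusted over the list alone. The mean change was 0.88 (camera adjusted p = 7.4e-19; adjusted p = 0.182 with an estimated correlation). GCLM, a subunit of the enzyme that makes glutathione, rose 4.15-fold (adjusted p = 0.0015). In the heat shock list 8 of 18 genes rose, 6 of them also without any 1 array, 14 when adjusted over the list alone (mean 0.81, camera adjusted p = 1.6e-24; adjusted p = 0.0502 with an estimated correlation). The co-chaperone genes CHORDC1 (5.55-fold, adjusted p = 6e-05), DNAJB1 (3.72-fold, adjusted p = 3.6e-05) and DNAJB4 (3.07-fold, adjusted p = 0.00091) led it. Among 10 metallothionein and zinc export genes 2 rose, also when adjusted over the list alone. Their mean was 0.51, or 0.88 without dim genes (camera adjusted p = 1e-05; adjusted p = 0.0502 with an estimated correlation). They were MT1F (3.13-fold, adjusted p = 0.014), lost without any control array or the first or second extract array (adjusted p 0.052 to 0.087), and the zinc exporter gene SLC30A1 (2.54-fold, adjusted p = 0.0076), lost without the second or the third extract array (adjusted p 0.054 and 0.055).

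In autophagy and lysosome 3 of 27 genes rose, 5 when adjusted over the list alone (mean 0.33, camera adjusted p = 6.1e-05; adjusted p = 0.712 with an estimated correlation), among them the autophagosome genes GABARAPL1 (4.59-fold, adjusted p = 0.0015) and MAP1LC3B (2.42-fold, adjusted p = 0.0029). The remaining call, SQSTM1, named post hoc, was lost without any control or extract array (adjusted p 0.052 to 0.068). Of 30 immediate early genes 4 rose and 1 fell, and adjusted over the list alone 9 rose and 3 fell (mean 0.45, camera adjusted p = 4.1e-07; adjusted p = 0.712 with an estimated correlation). DUSP1, a MAP kinase phosphatase gene, rose 3.2-fold (adjusted p = 2e-04) and ZFP36 2.83-fold (adjusted p = 0.0048), while NR4A2 rose 2.46-fold (adjusted p = 0.0011) and CCN1 fell 2.05-fold (adjusted p = 0.0032), the latter pair named post hoc. For p53 targets, 2 of 20 rose, and 3 rose and 1 fell when adjusted over the list alone. The list mean came to 0.15 (camera adjusted p = 0.04; adjusted p = 0.774 with an estimated correlation). That list call was lost without the second control array (adjusted p = 0.14), the first or the third extract array (0.086 and 0.07) or the first acid array (0.054). GADD45A rose 2.4-fold (adjusted p = 0.0017). TP53INP1, named post hoc, rose 1.69-fold (adjusted p = 0.032), lost without any control or extract array or the second acid array (adjusted p 0.058 to 0.17), while CDKN1A had a log2 fold change of 0.943 (adjusted p = 0.19). CDKN1A passed without the first acid array (0.0057) and with quantile normalization, median centring, array weights or only the 6 arrays compared (adjusted p 0.002 to 0.033). None of 11 AhR targets passed over all genes (3 higher at an unadjusted p under 0.05) and 2 rose when adjusted over the list alone (mean 0.15, camera adjusted p = 0.039; adjusted p = 0.712 with an estimated correlation), a list call lost without the second control array (0.12) or the second or the third extract array (0.06 and 0.078).

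Growth-related lists moved downward. Of 34 DNA replication genes 33 had a negative sign, none passed over all genes (12 lower before adjustment) and 8 fell when adjusted over the list alone (mean -0.41, camera adjusted p = 8.5e-13; adjusted p = 0.504 with an estimated correlation). GINS2, a subunit of the replicative helicase, had a log2 fold change of -0.993 (adjusted p = 0.25) and the cyclin gene CCNE2 of -0.739 (adjusted p = 0.053). GINS2 passed without the third acid array (0.032) and with quantile normalization, array weights or only the 6 arrays compared (adjusted p 0.013 to 0.05). CCNE2 passed without the first or second acid array (0.014 and 0.027), with quantile normalization, centring or array weights, without dim genes and with only the 6 arrays compared (adjusted p 0.0031 to 0.044). None of 33 mitosis genes passed by either adjustment, and 4 were lower before adjustment. Its mean was -0.13 (camera adjusted p = 0.0034; adjusted p = 0.774 with an estimated correlation). In ribosome biogenesis 1 of 31 genes fell, RRS1, and adjusted over the list alone also 1 (mean -0.22, camera adjusted p = 9e-05; adjusted p = 0.712 with an estimated correlation). The RRS1 call (2.2-fold, adjusted p = 0.046) was lost without any control array, the first or the third extract array or the second acid array (adjusted p 0.082 to 0.2), and MYC had a log2 fold change of 0.424 (adjusted p = 0.58; 0.047 with array weights and 0.024 with only the 6 arrays compared). No gene of 31 cytosolic ribosomal proteins passed by either adjustment, and 3 were lower before adjustment. The list averaged -0.19 (camera adjusted p = 9.4e-05; adjusted p = 0.712 with an estimated correlation).

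Downward shifts were called in 5 more lists. None of 28 interferon response genes passed over all genes (8 lower and 1 higher before adjustment) and 1 fell when adjusted over the list alone (mean -0.23, camera adjusted p = 0.00073; adjusted p = 0.712 with an estimated correlation). Among 19 TGF-beta targets ID1 and TGFB2 fell and TGIF1 rose, and adjusted over the list alone 6 fell and 1 rose (mean -0.27, camera adjusted p = 0.016; adjusted p = 0.712 with an estimated correlation), a list call lost without the third control array (0.062). The calls of TGFB2 and TGIF1 were lost without several control or extract arrays (adjusted p 0.052 to 0.072). Of 34 matrix and invasion genes THBS1 alone fell, named post hoc (1.48-fold, adjusted p = 0.049; lost without any control or extract array or the second acid array, adjusted p 0.073 to 0.22), and adjusted over the list alone 4 fell and 1 rose. The mean change was -0.14 (camera adjusted p = 0.0077; adjusted p = 0.726 with an estimated correlation). For liver X receptor (LXR) targets 2 of 11 fell, MYLIP and the cholesterol exporter gene ABCA1, and adjusted over the list alone 2 fell and 1 rose (mean -0.26, camera adjusted p = 0.022; adjusted p = 0.712 with an estimated correlation). Both gene calls were lost without any control or extract array (adjusted p 0.066 to 0.14). In hypoxia and glycolysis, of 29 genes the glucose transporter gene SLC2A3 rose (2.16-fold, adjusted p = 0.0086; lost without the second control array or the second or the third extract array, adjusted p 0.052 to 0.059) and LDHA, named post hoc, fell (1.5-fold, adjusted p = 0.031; lost without any control or extract array, adjusted p 0.086 to 0.15), and adjusted over the list alone 1 rose and 3 fell (mean -0.1, camera adjusted p = 0.046; adjusted p = 0.774 with an estimated correlation), a call lost without the first or the third control array, any extract array or the first acid array (adjusted p 0.058 to 0.088).

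Other settings, such as omitting dim genes and the replicate block, ended the calls of p53 targets (adjusted p 0.057 to 0.088), hypoxia and glycolysis (0.056 to 0.094) and AhR targets (0.057 and 0.094).

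The remaining 16 lists were not called with the extract. None of 22 pro-apoptotic genes passed over all genes (4 higher before adjustment), 2 were higher when adjusted over the list alone (camera adjusted p = 0.1), and none of 9 anti-apoptotic genes passed by either adjustment (1 higher before adjustment; camera adjusted p = 0.84). In lipid metabolism HSD17B7 alone rose among 21 cholesterol synthesis genes, 2 when adjusted over the list alone (camera adjusted p = 0.1). None of 16 fatty acid synthesis genes passed over all genes, with 1 higher and 1 lower both when adjusted over the list alone and before adjustment (camera adjusted p = 0.52). None of 20 PPAR and lipid oxidation genes passed over all genes (4 higher before adjustment), 2 when adjusted over the list alone, with a negative median beside a positive mean (camera adjusted p = 0.32). Among 17 one-carbon and serine genes PSAT1 (2.91-fold, adjusted p = 6.4e-05) and MTHFD2 (2.01-fold, adjusted p = 0.0077) rose, 3 when adjusted over the list alone (camera adjusted p = 0.1). The gene counts over all genes and adjusted over the list alone were both 1 higher, IL1A of 28 NF-kB cytokines (camera adjusted p = 0.13), PTGS2 of 20 eicosanoid synthesis genes (camera adjusted p = 0.38) and POR of 10 PXR and CAR targets (camera adjusted p = 0.63). PTGS2, the cyclooxygenase 2 gene, rose 2.84-fold (adjusted p = 0.0032). The calls of HSD17B7, IL1A, POR and MTHFD2 were lost without at least 3 arrays in turn (adjusted p 0.052 to 0.2), and these genes, PSAT1 and PTGS2 were named post hoc. None of 12 core and linker histone genes (camera adjusted p = 0.38), 28 proteasome genes (0.47), 26 oxidative phosphorylation genes (0.081) or 8 mitochondrially encoded genes (0.79, positive median beside a negative mean) passed by either adjustment or before adjustment. Oxidative phosphorylation was called without the third control array (0.025), the first extract array (0.022) or the third acid array (0.04) and with quantile normalization (0.04) or array weights (0.034), and eicosanoid synthesis without dim genes (0.041). Of the markers of other cell types, XBP1 rose among 19 luminal epithelial genes, 2 when adjusted over the list alone (camera adjusted p = 0.64, negative median beside a positive mean), while none of 19 blood cell genes (1 higher and 1 lower before adjustment; camera adjusted p = 0.86) and of 16 fibroblast and endothelial genes (0 before adjustment; camera adjusted p = 0.86) passed by either adjustment. ALOX5, the 5-lipoxygenase gene, had a log2 fold change of -0.0707 (adjusted p = 0.95) and CYP1A1 of -0.14 (adjusted p = 0.94).

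**Figure D2:**
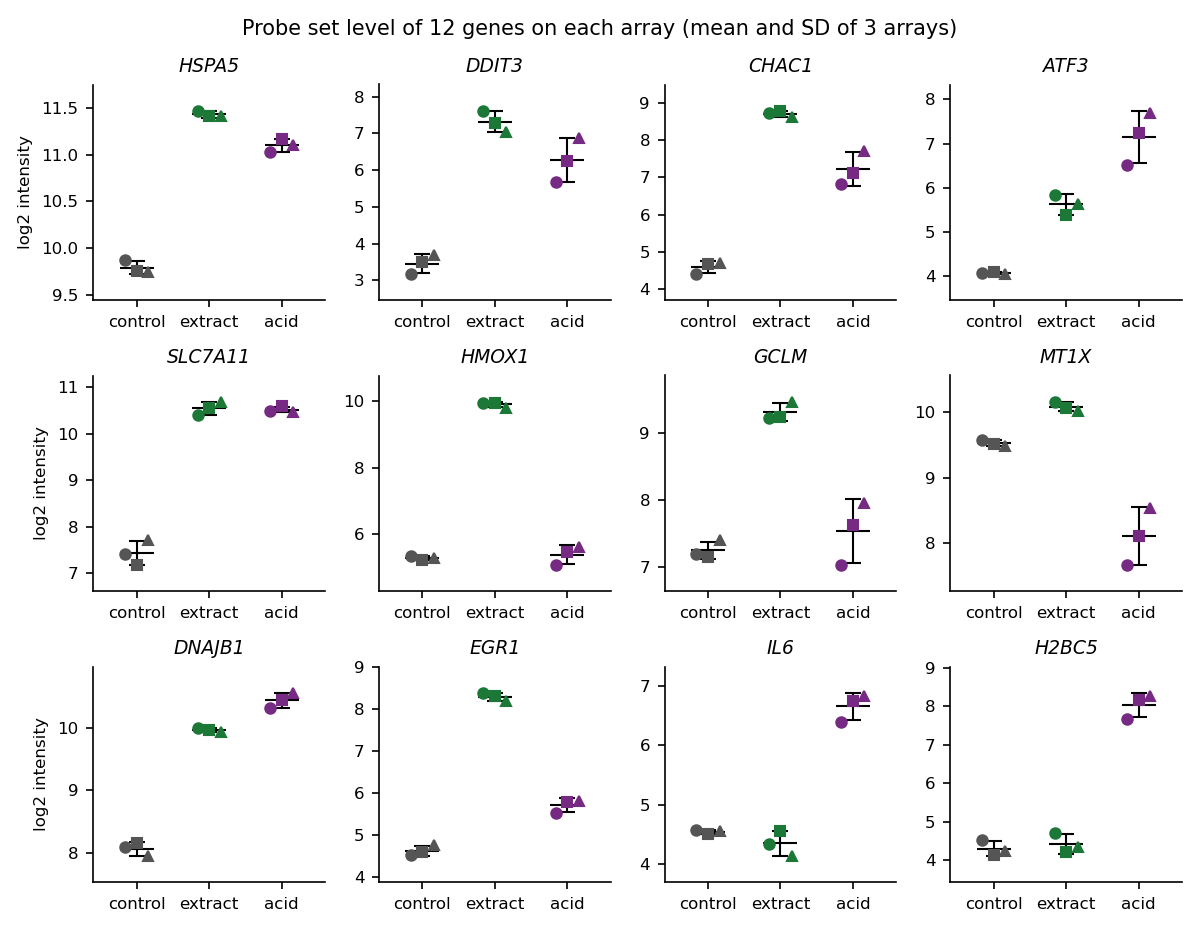
Log2 intensity of 12 genes on each of the 9 arrays, with points for single arrays and bars for the mean and SD of 3 arrays per group. HMOX1 lies near control with the acid (log2 fold change 0.0927) and 4.58 log2 units above it with the extract, whereas SLC7A11 rises by similar amounts with both (3.13 and 3.1).

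The acid raised histone, stress and immediate early genes. H1-6, a testis-type linker histone gene, rose at least 21.9-fold, from a dim log2 level of 2.26 to 6.71 (adjusted p = 9.6e-06), and the H2B histone genes H2BC18 and H2BC5 rose 13.4-fold each (3.74 ± 0.18 and 3.74 ± 0.19, adjusted p = 8.3e-06 and 1e-05). LURAP1L rose 13.2-fold (adjusted p = 2.6e-05), TCP11L2 12.1-fold (adjusted p = 2.9e-06), DUSP1 11.5-fold (adjusted p = 2.9e-06), EID3 11-fold (adjusted p = 1.7e-05) and SLC7A11 8.56-fold (adjusted p = 8.3e-06). CEMIP, a hyaluronan-degradation gene, was 8.62-fold lower than control (-3.11 ± 0.27, adjusted p = 0.00028). The transglutaminase gene TGM2 was 4.9-fold lower (adjusted p = 0.0018), TNFSF10, which encodes the death ligand TRAIL, 4.46-fold lower (adjusted p = 0.0011) and the transcription factor gene SOX9 4.12-fold lower (adjusted p = 0.001). IFI30 (4.1-fold, adjusted p = 0.0053), DNPH1 (3.92-fold, adjusted p = 0.0058; 0.055 with only the 6 arrays compared), ADAM19 (3.86-fold, adjusted p = 0.00063) and PMEPA1 (3.85-fold, adjusted p = 8e-04) fell as well. HMOX1 did not respond detectably (log2 fold change 0.0927, 95% interval -0.23 to 0.416, adjusted p = 0.76).

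Over all genes limma called 2044 with the acid, 624 higher and 1420 lower, of which 256 rose and 595 fell by at least 1 log2 unit. For 2041 of them the acid values lay beyond all control values, as for 25% of all genes, where chance gives 10%. The balance of rises and falls moved with the acid arrays: without the first, 2953 genes passed, 1563 higher and 1390 lower, 1846 of the 2044 among them, and without the third, 4229 passed, 629 higher and 3600 lower. It moved with other settings too, to 1857 higher and 2783 lower with quantile normalization and 1337 and 2171 with median centring, and with only the 6 arrays compared rises outnumbered falls, 193 against 162. Omitting the second acid array gave 740 genes, omitting a control array 650, 569 and 812, and omitting an extract array 1200, 1170 and 1233.

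The ER stress programme rose with the acid too. In the ISR list 14 of 27 genes rose, 16 when adjusted over the list alone (mean 1.1, camera adjusted p = 1e-19; adjusted p = 0.541 with an estimated correlation), and 12 of the 14 passed without any 1 array. ATF3 rose 8.44-fold (adjusted p = 0.00024), CTH 8.09-fold (adjusted p = 2.5e-05), SESN2 7.72-fold (adjusted p = 0.00022), DDIT3 7.07-fold (adjusted p = 0.00074) and CHAC1 6.18-fold (adjusted p = 0.00017). TRIB3 rose 1.98-fold (adjusted p = 0.045), a call lost without any control or extract array or the second acid array (adjusted p 0.078 to 0.14), and ATF4 had a log2 fold change of 0.19 (adjusted p = 0.45; 0.03 with quantile normalization and 0.017 with array weights). On the first, second and the third acid arrays the ISR list stood 0.741, 1.15 and 1.41 above control. Of 21 ER chaperone genes 8 rose, and adjusted over the list alone 9 rose and 2 fell (mean 0.4, camera adjusted p = 1.6e-05; adjusted p = 0.767 with an estimated correlation), with array means of 0.12, 0.48 and 0.6 and 4 of the 8 calls kept without any 1 array. DNAJB9 rose 7.22-fold (adjusted p = 1.7e-05), ERO1B 2.76-fold (adjusted p = 0.00024) and HSPA5 2.48-fold (adjusted p = 0.00014), while the 2.24-fold rise of XBP1 (adjusted p = 0.01) was lost without the first control array (0.05) or with only the 6 arrays compared (0.067). In ER-associated degradation 3 of 19 rose, 4 when adjusted over the list alone (mean 0.27, camera adjusted p = 0.00067; adjusted p = 0.767 with an estimated correlation), led by HERPUD1 (7.42-fold, adjusted p = 1e-05). Its array means were -0.091, 0.39 and 0.51, and the list mean moved to 0.45 without the first acid array, 0.15 without the third and 0.42 with quantile normalization. UFM1 and SEC24D lost their calls without the first or second control array or the second acid array, and SEC24D without the third control array too (adjusted p 0.055 to 0.086).

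Heat shock genes rose beside it, and amino acid genes less evenly. Of 19 tRNA synthetase genes 6 rose, and adjusted over the list alone 11 rose and 4 fell. The list mean stood at 0.14 (camera adjusted p = 0.00048; adjusted p = 0.767 with an estimated correlation), with array means of -0.2, 0.22 and 0.42. It was 0.32 without the first acid array, 0.0095 without the third, and 0.29, 0.23 and 0.22 with quantile normalization, centring and array weights. All 6 calls were lost without the first or second control array or the second acid array, among others (adjusted p 0.051 to 0.14). Among 15 amino acid transporters SLC7A11, SLC38A2 (2.91-fold, adjusted p = 7.7e-05) and SLC38A1 (1.75-fold, adjusted p = 0.0022) rose, and adjusted over the list alone 3 rose and 1 fell. Their mean was 0.27 and their median -0.032 (camera adjusted p = 0.01; adjusted p = 0.767 with an estimated correlation). That mean was 0.42 without the first acid array and 0.12, no longer called, without the third (adjusted p = 0.2). In the heat shock list 11 of 18 genes rose and 1 fell, also when adjusted over the list alone (mean 0.93, camera adjusted p = 1.4e-17; adjusted p = 0.171 with an estimated correlation). CHORDC1 rose 7.62-fold (adjusted p = 1.5e-05), DNAJB1 5.21-fold (adjusted p = 8.3e-06) and HSPA1L 4.19-fold (adjusted p = 7.8e-05). The fall was in HSF1, the gene of the heat shock transcription factor, named post hoc (1.78-fold lower, adjusted p = 0.024), lost without any control array or the second acid array (adjusted p 0.071 to 0.093).

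Inflammatory and immediate early genes rose in part. Of 30 immediate early genes 12 rose and 4 fell, 10 of the 16 also without any 1 array, and adjusted over the list alone 14 rose and 7 fell. The list mean came to 0.45 (camera adjusted p = 1.6e-06; adjusted p = 0.767 with an estimated correlation) and to 0.26 without the third acid array. Beside DUSP1, the nuclear receptor genes NR4A3 and NR4A2 rose at least 5.94-fold (from a dim 2.17, adjusted p = 0.00022) and 5.91-fold (adjusted p = 1e-05). The falls were FOSL1 (3.06-fold, adjusted p = 0.002), SPRY4 (3.25-fold, adjusted p = 0.0038), DUSP4 and DUSP6, named post hoc, the last pair losing their calls without at least 4 arrays in turn (adjusted p 0.055 to 0.12). In the NF-kB and cytokine list 7 of 28 rose and CSF1 fell, a call lost without 4 arrays in turn (adjusted p 0.053 to 0.089) and named post hoc, and adjusted over the list alone 7 rose and 3 fell. The cytokine genes CXCL8 (at least 5.35-fold, from a dim 2.17, adjusted p = 4e-04) and IL6 (4.32-fold, adjusted p = 9.5e-05) and the NF-kB inhibitor gene TNFAIP3 (3.08-fold, adjusted p = 0.0077; 0.06 with only the 6 arrays compared) led the rise, and 4 of the 8 calls were kept without any 1 array. Its mean was 0.2 and its median -0.053 (camera adjusted p = 0.015; adjusted p = 0.793 with an estimated correlation). That mean was 0.35 without the first acid array, 0.31 with quantile normalization, 0.13 without dim genes and 0.083, no longer called, without the third acid array (adjusted p = 0.1). Among 11 AhR targets 5 rose and 1 fell, also when adjusted over the list alone (mean 0.38, camera adjusted p = 0.00013; adjusted p = 0.767 with an estimated correlation). CYP1A1, the classical AhR-induced oxidase gene, rose 3.12-fold (adjusted p = 0.0016), TIPARP 2.03-fold (adjusted p = 0.0027) and CYP1B1 2-fold (adjusted p = 0.0021), and AHR (1.83-fold, adjusted p = 0.0018) and NFE2L2 rose too. CYP1B1, AHR and NFE2L2 were named post hoc, and NFE2L2 lost its call without 3 arrays in turn (adjusted p 0.054 to 0.064). NQO1 fell (2.01-fold, adjusted p = 0.02), lost without any control array or the second acid array (adjusted p 0.051 to 0.086).

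Core and linker histones were called with the acid, but not evenly. Of 12 measured genes 4 rose, H2BC5, H2BC21 (4.94-fold, adjusted p = 0.00063), H2AC6 (3.63-fold, adjusted p = 0.0013) and H2BC11 (3.22-fold, adjusted p = 0.0073), the last named post hoc. Each passed without any 1 array. Adjusted over the list alone 4 rose and 2 fell, and the mean of 0.46 stood beside a median of -0.34 (camera adjusted p = 0.028; adjusted p = 0.793 with an estimated correlation). The list call was lost without the third control array (adjusted p = 0.11), the third extract array (0.061) or the third acid array (0.07, mean 0.29), and with quantile normalization (0.1), median centring (0.084) or array weights (0.26). Whether probes tell these near-identical genes apart was not tested.

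Metallothionein, LXR and interferon genes fell too. Of 10 metallothionein and zinc export genes 4 fell, each also without any 1 array, and 5 when adjusted over the list alone. Its mean was -0.52 (camera adjusted p = 0.039; adjusted p = 0.667 with an estimated correlation). MT1E was 3.26-fold lower (adjusted p = 0.0046), MT1X 2.69-fold (adjusted p = 0.0035), MT1M at least 2.11-fold (to a dim 2.33, adjusted p = 0.0032) and MT2A, named post hoc, 1.66-fold (adjusted p = 0.0048). The list call was lost without the third control array (0.086) or the second or the third acid array (0.061 and 0.2) and without dim genes (0.068, mean -0.82), and these genes too are near-identical. For LXR targets 3 of 11 fell, 5 when adjusted over the list alone (mean -0.49, camera adjusted p = 0.014; adjusted p = 0.767 with an estimated correlation), with ABCA1 3.17-fold lower (adjusted p = 0.0014). The falls of PLTP and SCD, the latter named post hoc, were lost without any control or extract array or the second acid array (adjusted p 0.051 to 0.12). In the interferon response 7 of 28 fell, 10 when adjusted over the list alone (mean -0.41, camera adjusted p = 0.0044; adjusted p = 0.767 with an estimated correlation). Its array means were -0.72, -0.32 and -0.2, and the list mean was -0.26 without the first acid array (camera adjusted p = 0.038). IFI27, the only 1 of the 7 to pass without any 1 array, was 2.15-fold lower (adjusted p = 0.0044), while IFI6 and IFIT3 lost their calls without any control array, among others (adjusted p 0.052 to 0.11).

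Matrix and TGF-beta genes fell. Of 34 matrix and invasion genes 13 fell, 7 of them also without any 1 array, and adjusted over the list alone 15 fell and 1 rose. The list averaged -0.53 (camera adjusted p = 4.8e-05; adjusted p = 0.767 with an estimated correlation). PLAU, the urokinase gene, was 3.67-fold lower (adjusted p = 0.00092), TGFBI 3.36-fold (adjusted p = 0.00014) and the mesenchymal transcription factor gene SNAI2 3.18-fold (adjusted p = 0.0037). Among 19 TGF-beta targets 5 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose (mean -0.51, camera adjusted p = 0.026; adjusted p = 0.793 with an estimated correlation), with PMEPA1, ANGPTL4 (2.93-fold, adjusted p = 0.0058; 0.051 with only the 6 arrays compared) and COL4A1 (2.36-fold, adjusted p = 0.0017) lower. SMAD6 fell and TGIF1 rose with calls lost without 4 arrays in turn (adjusted p 0.052 to 0.099), and these and COL4A1 were named post hoc. That list call was lost without the third control array (0.074), and ID1 (2.65-fold lower, adjusted p = 0.013) lost its call without the second or the third control array (0.07 and 0.052).

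Growth and energy lists fell, most on the first acid array, whose intensities stood apart. DNA replication had 8 of 34 genes lower, 20 when adjusted over the list alone (mean -0.6, camera adjusted p = 1.3e-05; adjusted p = 0.767 with an estimated correlation), with means of -1.1, -0.47 and -0.25 on the first, second and the third acid arrays. Oxidative phosphorylation had 8 of 26 lower, and adjusted over the list alone 17 lower and 1 higher (mean -0.53, camera adjusted p = 5.6e-05; adjusted p = 0.767 with an estimated correlation). The proteasome had 2 of 28 lower, PSMB2 and PSMD8, named post hoc, and 11 when adjusted over the list alone (mean -0.43, camera adjusted p = 0.001; adjusted p = 0.804 with an estimated correlation). Hypoxia and glycolysis had 10 of 29 lower and SLC2A3 higher, named post hoc (adjusted p = 0.029; up to 0.11 without 1 array), and adjusted over the list alone 14 lower and 2 higher (mean -0.35, camera adjusted p = 0.0023; adjusted p = 0.793 with an estimated correlation), with PGAM1 2.03-fold lower (adjusted p = 0.0076). Ribosome biogenesis had 8 of 31 lower and 1 higher, and adjusted over the list alone 13 lower and 1 higher (mean -0.44, camera adjusted p = 0.0056; adjusted p = 0.835 with an estimated correlation). The higher gene was MYC (1.77-fold, adjusted p = 0.031), lost without any control or extract array or the second acid array (adjusted p 0.059 to 0.11). Ribosomal proteins had RPS19 and RPL24 lower of 31 genes, also 2 when adjusted over the list alone, each call lost without at least 5 arrays in turn (adjusted p 0.052 to 0.14), with RPL24 named post hoc. The mean change was -0.28 (camera adjusted p = 0.014; adjusted p = 0.835 with an estimated correlation).

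Without the first acid array these lists kept their negative means at smaller size. They were -0.36 for DNA replication (camera adjusted p = 2e-05, 10 genes lower), -0.34 for oxidative phosphorylation (0.00068, 5 lower), -0.21 for the proteasome (0.018, 0 lower), -0.21 for hypoxia and glycolysis (0.016, 9 lower) and -0.22 for ribosome biogenesis (0.031, 6 lower), while ribosomal proteins were no longer called (-0.14, 0.091). In these 6 lists PGAM1 alone of the gene calls passed without any 1 array (adjusted p up to 0.16 for the others). With quantile normalization the means of ribosome biogenesis, the proteasome, hypoxia and glycolysis and ribosomal proteins were -0.28, -0.27, -0.2 and -0.13. List calls with the acid were also ended by array weights for amino acid transporters (adjusted p = 0.32), NF-kB cytokines (0.17) and the interferon response (0.061) and by omitting dim genes for LXR targets (0.088), ribosome biogenesis (0.075) and the proteasome (0.054). At least 2 settings each ended those of metallothioneins (0.068 to 0.12), TGF-beta targets (0.057 to 0.083), hypoxia and glycolysis (0.054 and 0.12) and ribosomal proteins (0.29 and 0.39).

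The other lists were not called with the acid. NRF2 targets had 5 of 25 genes higher and 3 lower, 5 and 4 when adjusted over the list alone, a mean of -0.02 and a median of -0.22 beside an upward test (camera adjusted p = 0.49), with array means of -0.39, 0.052 and 0.28. SLC7A11, TXNRD1 (2.5-fold, adjusted p = 0.00034), UGDH, ABCC2 and GCLC rose and NQO1, TKT and ABCC3 fell, and apart from SLC7A11 and NQO1 these genes were named post hoc. GCLC, TKT and ABCC3 lost their calls without at least 2 arrays in turn (adjusted p 0.051 to 0.14). Among 22 pro-apoptotic genes PMAIP1 rose (1.72-fold, adjusted p = 0.01) and 6 fell, among them the BCL2 family effector genes BAX (2.44-fold, adjusted p = 0.016) and BAK1 (2.48-fold, adjusted p = 0.0089), and adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.69). Each of these 7 calls was lost without at least 1 array (adjusted p 0.051 to 0.14), and the genes were named post hoc. Of 9 anti-apoptotic genes BCL2L1 fell by both adjustments (1.97-fold, adjusted p = 0.0059; camera adjusted p = 0.79). Autophagy had 4 of 27 genes higher, GABARAPL1, MAP1LC3B, TAX1BP1 and ATG12, and CTSB and GABARAP lower, 6 and 9 when adjusted over the list alone (camera adjusted p = 0.7). Among 20 p53 targets GADD45A, TP53INP1 and SESN1 rose and BAX fell, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.09; 0.048 and 0.017 without the first control or acid array and 0.027 with quantile normalization). The one-carbon and serine list had PSAT1 and MTHFD2 higher of 17 genes, 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.25). In the anti-apoptotic, autophagy, p53 and one-carbon lists the mean was negative while the test pointed upward, and their genes were named post hoc. The calls of ATG12, CTSB, GABARAP, TP53INP1 and SESN1 were lost without at least 3 arrays in turn (adjusted p 0.05 to 0.15).

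Mitosis had 6 of 33 genes lower with the acid, 7 when adjusted over the list alone (camera adjusted p = 0.12; 0.0077 without the second acid array), led by CDC20 (2.3-fold, adjusted p = 0.0021), named post hoc. Fatty acid synthesis had FASN and SCD lower of 16 genes, 5 when adjusted over the list alone (camera adjusted p = 0.09; 0.038 without the third acid array). Of 21 cholesterol synthesis genes INSIG1, SC5D and HSD17B7 rose and ERG28, ACAT2, TMEM97, EBP and FDPS fell, 3 and 7 when adjusted over the list alone (camera adjusted p = 0.7). All 8 calls were lost without at least 1 array (adjusted p 0.051 to 0.12). PPAR and lipid oxidation had PDK4 higher and ANGPTL4 lower of 20 genes, 2 and 2 when adjusted over the list alone (camera adjusted p = 0.97, upward beside a negative mean). In eicosanoid synthesis, of 20 genes PTGS2 rose 7.21-fold (adjusted p = 4e-05) and ALOX5AP, which encodes the activating protein of 5-lipoxygenase, fell 1.86-fold (adjusted p = 0.0073), 3 and 3 when adjusted over the list alone (camera adjusted p = 0.51, 0.048 without dim genes, negative median beside a positive mean). Mitochondrially encoded genes had ND3 lower of 8, 2 when adjusted over the list alone (camera adjusted p = 0.93, positive median beside a negative mean), and PXR and CAR targets CYP2B6 lower of 10 by both adjustments (camera adjusted p = 0.96). Among luminal epithelial markers AGR2 (4.15-fold, adjusted p = 0.0004), XBP1 and CDH1 rose and GATA3 fell of 19 genes, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.71, upward beside a negative mean). Of 19 blood cell genes CD68 fell by both adjustments (camera adjusted p = 0.9), and of 16 fibroblast and endothelial genes none passed by either adjustment (1 lower before adjustment; camera adjusted p = 0.97, upward beside a negative mean). The calls of FASN, SCD, ND3, CYP2B6, CDH1, GATA3 and CD68 were lost without at least 2 arrays in turn (adjusted p 0.051 to 0.12), and these lists' genes were named post hoc. CDKN1A had a log2 fold change of 0.127 (adjusted p = 0.83; 0.041 with array weights) and ALOX5 of -0.363 (adjusted p = 0.078; 0.039 with quantile normalization and 0.00092 with array weights).

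**Figure D3:**
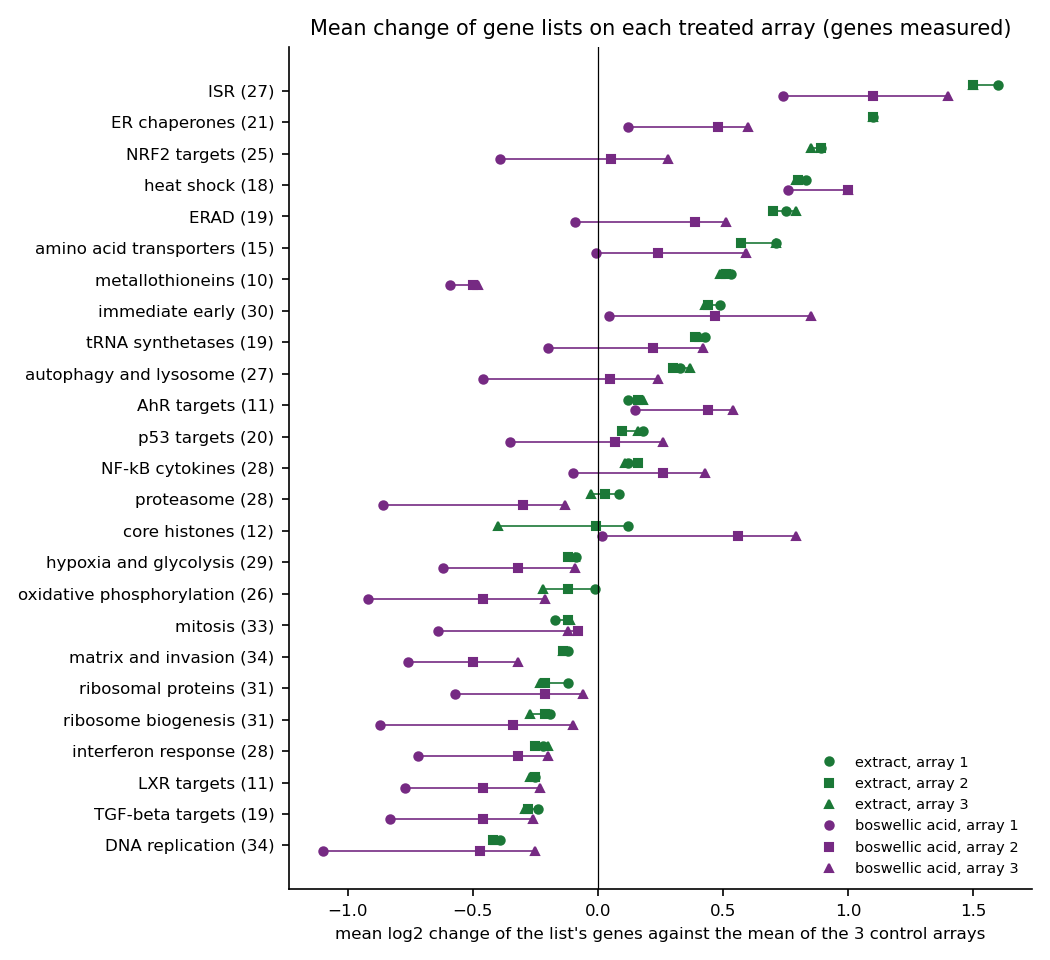
Mean log2 change against the control mean of every gene list called with the extract or the acid, with the number of measured genes in brackets and 1 point per treated array. The first acid array lies below the other two in lists such as DNA replication (-1.1 against -0.47 and -0.25).

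Both treatments changed 154 genes the same way, 122 higher and 32 lower, where independent lists of these sizes would share 5.63 and 2.92. Simulated unchanged groups with 3 shared controls had 0 in all 100 draws, no benchmark as nothing changed there. Part of the excess may come from the shared controls, too few to split. Omitting a control array left 65, 65 and 98 shared genes, an extract array 81, 69 and 67, and the first or second acid array 536 and 102. Over all genes 65.3% had the same sign in both comparisons, against 66.6% in the simulation. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.518 and Spearman rho = 0.468, against 0.5 and 0.474 in the simulation. Their covariance was 0.0626 against a simulated 0.0166, a difference of 0.046. Only CCN1, a matricellular growth factor gene named post hoc, was called in opposite directions and fell with the extract (-1.03 ± 0.12 SE, adjusted p = 0.0032) and rose with the acid (0.492 ± 0.12, adjusted p = 0.036; lost without any control or extract array or the second acid array, adjusted p 0.06 to 0.12).

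**Figure D4:**
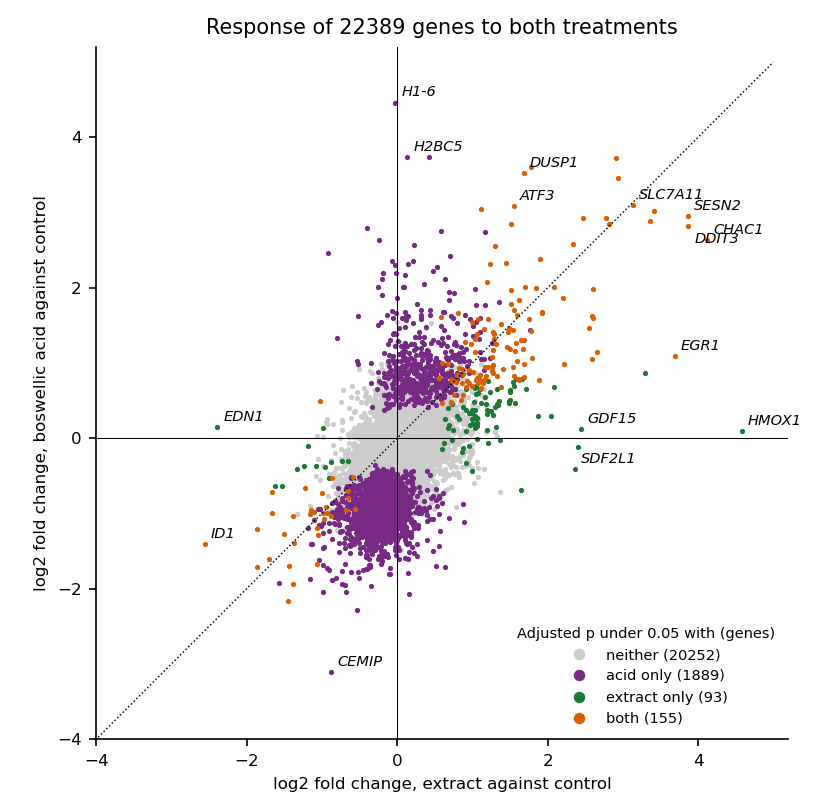
Log2 fold change with the extract (horizontal) against that with the acid (vertical) for 22389 genes, equality dotted. Calls come from the fit to all 9 arrays. Colours mark the 154 genes called the same way and the 1 called in opposite directions in both comparisons, the 93 called with the extract alone and the 1889 called with the acid alone, and HMOX1 lies far right near 0 vertically.

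Compared directly at unequal doses and in different solvents, the acid and the extract differed in histone, antioxidant and metal-binding genes. H1-6 was at least 22.4-fold higher with the acid, against a dim log2 level of 2.22 with the extract (adjusted p = 2.1e-05), H2BC5 12.2-fold (3.61, 3.18 to 4.04, adjusted p = 3.2e-05) and H2BC18 9.98-fold (3.32, 2.93 to 3.71, adjusted p = 3.2e-05). The protease gene ADAMTS1 (10.4-fold, adjusted p = 0.00077), the olfactory receptor gene OR5P2 (at least 9.17-fold, against a dim 2.23 with the extract, adjusted p = 0.00021) and EDN1 (5.83-fold, adjusted p = 0.0023) were higher with the acid as well. HMOX1 was 22.4-fold lower with the acid (-4.49, -4.81 to -4.16, adjusted p = 1.4e-06), SDF2L1 6.82-fold (-2.77, -3.27 to -2.26, adjusted p = 0.00051) and EGR1 6.03-fold (-2.59, -2.87 to -2.32, adjusted p = 2.1e-05). HKDC1 (5.73-fold, adjusted p = 0.00077), NMRAL2P (5.38-fold, adjusted p = 0.0016) and MT1E (5.1-fold, adjusted p = 0.0018) were lower too.

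In all, limma called 1007 genes between acid and extract, 258 higher and 749 lower with the acid, of which 112 and 363 differed by at least 1 log2 unit. All 1007 had acid values beyond all extract values, as did 21.9% of all genes, where chance gives 10%. With quantile normalization 1282 were higher and 1796 lower, a lower share of 58.3% against 74.4%, and with only the 6 arrays compared 62 were higher and 65 lower (51.2%). Without the first acid array 1764 genes passed, 903 higher and 861 lower, 953 of the 1007 among them. Omitting the second acid array gave 228 and the third 3521, an extract array 162, 179 and 223, and a control array 495, 511 and 550.

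Antioxidant and metal-binding genes were lower with the acid than with the extract. Of 25 NRF2 targets 12 were lower and 1 higher, and adjusted over the list alone 17 lower and 1 higher (mean -0.9, camera adjusted p = 3e-07; adjusted p = 0.994 with an estimated correlation). Of the 13 calls 4 passed without any 1 array (adjusted p up to 0.16 for the others). SRXN1, the sulfiredoxin gene, differed by -2.09 (95% interval -2.72 to -1.47, adjusted p = 0.0054), GCLM by -1.76 (-2.24 to -1.29, adjusted p = 0.0032) and NQO1 by -1.57 (-2.04 to -1.1, adjusted p = 0.0054), and SRXN1 and NQO1 lost their calls with only the 6 arrays compared (0.056 and 0.058). The higher gene, ABCC2 (0.566, adjusted p = 0.045), named post hoc, lost its call without 7 arrays in turn (adjusted p 0.081 to 0.15). Among 10 metallothionein and zinc export genes 6 were lower, 7 when adjusted over the list alone (mean -1, camera adjusted p = 4.9e-06; adjusted p = 0.068 with an estimated correlation), with MT1F at -2.34 (-2.9 to -1.77, adjusted p = 0.0019) and MT1X at -1.98 (-2.41 to -1.56, adjusted p = 0.0012). Without the first acid array the means were -0.71 (camera adjusted p = 2.6e-08) and -1 (9.5e-07), and without dim genes the latter was -1.7.

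ER stress lists were also lower with the acid. Of 21 ER chaperone genes 10 were lower, 2 of them also without any 1 array (adjusted p up to 0.15 for the others), and 13 when adjusted over the list alone. The list mean stood at -0.68 (camera adjusted p = 3.7e-07; adjusted p = 0.994 with an estimated correlation). PDIA4 and CRELD2, behind SDF2L1, differed by -1.38 and -1.13 (adjusted p = 0.012 and 0.02), calls lost without any extract array or the second acid array (adjusted p 0.05 to 0.094). In ER-associated degradation 3 of 19 were lower, 11 when adjusted over the list alone (mean -0.48, camera adjusted p = 0.0012; adjusted p = 0.994 with an estimated correlation), with SYVN1, an ER ubiquitin ligase gene, at -1.62 (-2.09 to -1.14, adjusted p = 0.005) and with DERL3 and SEC24D losing their calls without at least 3 arrays in turn (adjusted p 0.051 to 0.1), DERL3 named post hoc. In the ISR list 4 of 27 were lower and 1 higher, and adjusted over the list alone 14 lower and 1 higher (mean -0.45, camera adjusted p = 0.0019; adjusted p = 0.994 with an estimated correlation). GDF15 differed by -2.32 (-2.75 to -1.9, adjusted p = 0.00051) and CHAC1 by -1.49 (-1.95 to -1.04, adjusted p = 0.0061). TRIB3 and PSAT1 lost their calls without at least 4 arrays in turn (adjusted p 0.057 to 0.12), both named post hoc. ATF3 was the higher gene at 1.53 (0.96 to 2.1, adjusted p = 0.014), lost without any extract array or the second acid array (adjusted p 0.055 to 0.073). SYVN1 and CHAC1 lost their calls with only the 6 arrays compared (0.053 and 0.054). Without the first acid array the 3 means were -0.55, -0.3 and -0.27 (camera adjusted p = 1e-06, 0.0033 and 0.0065), the latter pair -0.31 and -0.3 with quantile normalization too.

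Of the 33 genes named in both comparisons with control, 14 differed between acid and extract and 19 did not pass, and the genes singled out here were named post hoc. DUSP1 was higher with the acid by 1.84 (95% interval 1.55 to 2.13, adjusted p = 0.00021) and ERO1B lower, at -1.08 (-1.36 to -0.813, adjusted p = 0.0023). Other stress genes gave no detectable difference. For SLC7A11 the difference was -0.0301 (95% interval -0.355 to 0.295, adjusted p = 0.93), for DNAJB9 0.0302 (-0.322 to 0.383, adjusted p = 0.94) and for XBP1 -0.104 (-0.561 to 0.352, adjusted p = 0.82). The intervals of HSPA5 (-0.55 to -0.108, adjusted p = 0.095), HERPUD1 (-0.8 to -0.146, adjusted p = 0.1), SESN2 (-1.45 to -0.372, adjusted p = 0.065) and DDIT3 (-1.67 to -0.419, adjusted p = 0.068) lay below 0, but none passed.

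Other lists differed in both directions. AhR targets had 3 of 11 higher and 1 lower, and adjusted over the list alone 4 higher and 1 lower (mean 0.22, 0.14 without the third acid array, camera adjusted p = 0.003; adjusted p = 0.994 with an estimated correlation), with CYP1A1 3.44-fold (adjusted p = 0.0018), CYP1B1 2.06-fold (adjusted p = 0.0029) and TIPARP 2.03-fold (adjusted p = 0.0044) higher with the acid and NQO1 lower, TIPARP named post hoc. Heat shock had HSPA1L and DNAJB1 higher and HSF1 lower of 18 genes, calls lost without at least 4 arrays in turn (adjusted p 0.051 to 0.13), DNAJB1 named post hoc. Adjusted over the list alone, 7 were higher and 1 lower. The list mean came to 0.12 (camera adjusted p = 0.0015; adjusted p = 0.994 with an estimated correlation), 0.2 without the first and 0.076 without the third acid array, and 0.2 to 0.23 with other scalings or array weights. Core and linker histones had 4 of 12 higher, and adjusted over the list alone 5 higher and 2 lower, with a mean of 0.55 beside a median of -0.047 (camera adjusted p = 0.0015, 0.055 without the third extract array; adjusted p = 0.994 with an estimated correlation). H2BC21 was 5.04-fold higher with the acid (adjusted p = 0.0011), H2AC6 3.63-fold (adjusted p = 0.0021) and H2BC11, named post hoc, 3.39-fold (adjusted p = 0.011; 0.059 and 0.069 without 2 arrays in turn). Of 30 immediate early genes 7 were higher and 6 lower, 9 and 8 when adjusted over the list alone (mean 0.003, camera adjusted p = 0.036; adjusted p = 0.994 with an estimated correlation). Its array means were -0.41, 0.016 and 0.4, so the sign of the mean rests on single arrays. It was 0.21 without the first acid array (11 higher, 7 lower) and -0.2 without the third (0.38), and the call was also lost without the third extract array (0.06). Of the 13 gene calls 9 passed without any 1 array. NR4A3 was at least 5.08-fold higher (against a dim 2.39 with the extract, adjusted p = 0.00077) and SPRY4, a growth factor signalling inhibitor gene, 4.64-fold lower (adjusted p = 0.0018).

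Another 5 lists were lower with the acid. Matrix and invasion had 8 of 34 genes lower, 12 when adjusted over the list alone (mean -0.39, camera adjusted p = 0.0015; adjusted p = 0.994 with an estimated correlation). TGFBI (2.46-fold lower, adjusted p = 0.0016) and TIMP1, named post hoc, alone passed without any 1 array (adjusted p up to 0.15 for the others). The proteasome had all 28 genes negative in sign, 0 passing over all genes (18 lower before adjustment) and 6 lower when adjusted over the list alone. Its mean was -0.46 (camera adjusted p = 5e-05; adjusted p = 0.994 with an estimated correlation). Oxidative phosphorylation had 0 of 26 passing by either adjustment and 16 lower before adjustment (mean -0.41, camera adjusted p = 0.0014; adjusted p = 0.994 with an estimated correlation). Autophagy and lysosome had CTSL and WIPI1 lower and TAX1BP1 higher of 27 genes, calls lost without at least 4 arrays in turn (adjusted p 0.056 to 0.14), TAX1BP1 named post hoc. Adjusted over the list alone, 10 were lower and 1 higher. The list averaged -0.39 (camera adjusted p = 0.0053, 0.052 without the first acid array; adjusted p = 0.994 with an estimated correlation). Cholesterol synthesis had PMVK lower of 21 genes (lost without 7 arrays in turn, adjusted p 0.069 to 0.16) and 3 when adjusted over the list alone (mean -0.39, camera adjusted p = 0.03, 0.11 without the first acid array and 0.064 without the third extract array; adjusted p = 0.994 with an estimated correlation). Without the first acid array the means were -0.24 for the proteasome, -0.22 for oxidative phosphorylation and -0.19 each for autophagy and cholesterol synthesis. With quantile normalization the 4 means lay between -0.29 and -0.2. Array weights or omitting dim genes ended the calls of oxidative phosphorylation (0.062), autophagy (0.052 and 0.18), cholesterol synthesis (0.24), histones (0.075) and AhR targets (0.056), and quantile normalization, centring or weights that of immediate early genes (0.073 to 0.38). The other 23 lists were not called between the treatments, among them pro-apoptotic genes (camera adjusted p = 0.08; 0.048 and 0.038 without the second or the third acid array and 0.039 with centring) and DNA replication (camera adjusted p = 0.96, upward beside a negative mean). Without the third acid array hypoxia and glycolysis (0.0079), amino acid transporters (0.043) and tRNA synthetases (0.048) were called too.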

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

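Of the tests below, those of a stronger and of a lower response to the acid, of a uniform shift behind the NRF2 and metallothionein lists and of a stop of DNA replication shared by both treatments were chosen after the result was seen.

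Probe sets outside the annotation, which no comparison used, also changed. Among 27904 of them, limma called 83 higher and 27 lower with the extract and 478 higher and 255 lower with the acid, with log2 fold changes of -3.25 to 2.83 and -3.16 to 5.23. Which transcripts they measure was not tested.

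More genes fell than rose with the acid, 1420 against 624. Without the first acid array the ratio of falls to rises was 0.889, so that array may be the source. With only the 6 arrays compared, 193 rose and 162 fell, which cannot tell, as that array widens the spread. Centring each array on its median left a ratio of 1.62, which argues against one uniform shift of that array as the whole cause. A stronger response in that sample stays open, since the ISR list stood lower there than on the other two acid arrays (log2 difference -0.537) by as much as random lists of like level (percentile 54 of 10000). Lower RNA quality stays open, as no label covers it.

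NRF2 targets and metallothioneins were higher with the extract than with the acid. The larger camera adjusted p of the 2 lists was 9.5e-07 without the first acid array, which argues against that array as the cause, and with arrays centred on the median their mean differences were still -0.82 and -0.96 (SD 0.21 and 0.075 over the acid arrays), which argues against a uniform shift. A lower response to the acid in general is argued against too, since the ratio of acid to extract change was -0.023 for NRF2 targets (95% bootstrap interval -0.55 to 0.34) and 0.71 for the ISR list (0.53 to 0.86), a difference of -0.73. Different compounds, doses and solvents remain as open explanations, as untested, and probes shared between metallothionein copies were not tested.

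Of 12 core and linker histone genes 4 were higher with the acid than with control, at a list median of -0.34, and 4 than with the extract (median -0.047). The list's camera adjusted p was 0.031 without the first acid array, which argues against that array as the source. A stop of DNA replication shared by both treatments stays open: the list's mean change with the extract over that with the acid was -0.21 (0.13 without the third extract array), but that change, -0.095 with an SD of 0.27 over arrays, lay within 1 SD of a bound at 0.15. A rise of all dim probe sets is argued against, as the mean stood at percentile 99.97 of 10000 random lists matched on level. The list call against control was lost with an estimated correlation (adjusted p = 0.793), under quantile normalization (0.1), centring (0.084) and array weights (0.26), and probes shared between histone copies may contribute.

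For gene counts, the 10 splits of 6 arrays were too few for a share under 0.05, and the real split was the only 1 of the 10 to give as many genes, with 248, 2044 and 1007 genes for extract, acid and their difference against 0 in the highest other split. The same held for gene lists, with 21, 21 and 14 lists called by the real split against at most 9, 11 and 9. Of 100 regroupings of the 9 arrays, only the real one reached the 154 genes changed the same way by both treatments (highest other 69). For the covariance, 6 were as large as the real 0.0626 (highest other 0.0878). Regroupings mix treated and control arrays, so neither count decides whether responses overlap by chance.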

How the results depend on the processing

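All alternatives here were chosen before the data were examined. No named gene or gene list reversed a call. Named genes gave the same verdict in 1198 of 1402 values for the extract (85 lost and 119 gained the call), in 1289 of 1508 for the acid (170 and 49) and in 765 of 880 for their difference (71 and 44). Of the named genes called with all 9 arrays, 26 with the acid, 15 for the difference and 0 with the extract lost their calls with only the 6 arrays compared, and 12, 3 and 4 did so with all probe sets tested. Gene lists gave the same verdict in 597, 591 and 616 of 663 values each. No scaling moved the median of all genes by more than 0.1 or turned the mean of a called list. Gene counts for the extract, the acid and their difference were 1003, 4640 and 3078 with quantile normalization, 605, 3508 and 2191 with median centring, 1296, 9785 and 9434 with array weights, and 1055, 355 and 127 with the 6 arrays compared alone, where fewer arrays estimate the spread. The difference gave 1623 genes when dim genes were left out, and the genes shared by both treatments numbered 660, 375 and 938 with quantile normalization, centring and weights. With array weights the share of lower calls was 35.7% for the extract and 61.1% for the difference. The weights were 31.4 for the second acid array and 0.11 and 0.288 for the first and the third, so that fit rests largely on 1 acid array. The covariance was 0.0682 with weights and 0.11 without dim genes. Leaving out 1 array gave 97 to 888 genes for the extract, 569 to 4229 for the acid, 162 to 3521 for the difference and 65 to 536 shared, with a covariance of 0.0593 to 0.0754. An estimated correlation left 0, 0 and 0 lists, and fry, which tests a list without comparing it with other genes, called 7, 8 and 3. Numbers did not pair the arrays (same-number correlations from -0.14 to 0.22, and 2 of 9 arrays matched their own number best in both other groups). With the replicate block the counts were 270, 1995 and 1003 genes, 165 shared, and 18, 20 and 14 lists. The cause of these moves was not tested. Signal over background limits what dim probe sets can show.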

Other observations

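The 10 gene families below were chosen by name after the values were seen, and so were all tests on them. Of 68 genes of the mitochondrial ribosome 20 fell and 0 rose with the acid (mean log2 fold change -0.58, camera adjusted p = 8.7e-10 over the 10 families; adjusted p = 0.51 with an estimated correlation). The mean was -0.35 without the first acid array (camera adjusted p = 6.7e-08) and -0.43, -0.49 and -0.46 with quantile normalization, centring and array weights. With the extract the mean was -0.18 and 0 genes passed in limma (camera adjusted p = 0.00019; adjusted p = 0.97 with an estimated correlation). Between acid and extract MRPL2, MRPL24, MRPL36 and MRPL52 were lower (mean -0.4, camera adjusted p = 3.7e-05; adjusted p = 0.69 with an estimated correlation), with means of -0.18 without the first acid array (camera adjusted p = 0.0085) and -0.23 with quantile normalization.

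Among all 47 measured histone genes 8 rose and H2AX fell with the acid (mean 0.34, camera adjusted p = 0.00068; adjusted p = 0.51 with an estimated correlation), and 0 passed with the extract (mean -0.022). Of 23 bitter taste receptor genes TAS2R10 alone rose with the acid (mean 0.21, 0.34 without the first acid array and 0.45 with array weights; camera adjusted p = 0.0022; adjusted p = 0.51 with an estimated correlation). Of 383 olfactory receptor genes OR2B6, OR5P2, OR5P3 and OR9A4 rose and OR7E14P fell with the acid. That family alone was called with an estimated correlation too (camera adjusted p = 0.024 and 0.016), at a mean of 0.0045 (0.033, 0.091 and 0.0022 with quantile normalization, centring and array weights), but not without the first acid array (0.81). Zinc finger genes were called upward with the extract (435 genes, mean 0.1, camera adjusted p = 0.0051; adjusted p = 0.97 with an estimated correlation) and with the acid (camera adjusted p = 0.01; adjusted p = 0.95 with an estimated correlation), where the mean was -0.0041 (0.089, 0.082 and 0.13 with those settings, 0.14 without the first acid array). Solute carrier genes, sprouty and dual-specificity phosphatase genes, microRNA genes, snoRNAs and keratin-associated protein genes were not called with either treatment.

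The acid arrays differed in how they followed the calls made without them. Of 1390 genes lower without the first acid array, 99.6% were lower on it too, at a median of -1.38 against -0.719 on the other two. Of 1563 genes higher without it, 76.1% were higher on it, at a median of 0.229 against 0.766. For the second acid array the 299 higher genes stood at 1.41 against 1.12 and the 441 lower ones at -1.03 against -1.14. Of 3600 genes lower without the third acid array, 88.6% were lower on it, at a median of -0.279 against -0.915, while the 629 higher ones stood at 0.953 against 0.874.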
